A study of Mus musculus with 8 samples.

How the data were processed

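Total RNA of mouse embryonic fibroblasts of 4 genotypes, mock transfected or transfected with B-DNA for 4 h, was measured on 8 one-colour Affymetrix arrays, 1 for each combination. The deposited values are MAS5 signal intensity per probe set on a linear scale, made by the authors with Microarray Suite 5.0, per the labels and the design text. Any scaling target, detection calls and pooling of cultures are not given in the sources used here, and GeneSpring is named there with no role stated. The design text names another array type than the one the probe set names belong to, and gene names were taken from the annotation that matched the probe set names. The intensity of the deposited arrays was not set to a common level, with 2% trimmed means from 140 to 255, so each array was multiplied by a factor (1.96 to 3.58) that brought this mean to 500. The ratio of 3' to 5' signal lay between 0.78 and 0.92 for Gapdh and between 0.94 and 1.32 for Actb.

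Of 22690 probe sets, 64 were controls and 22626 were used. Of these, 20380 were annotated with 1 gene symbol, 691 with several and 1555 with none in the table used here. Symbols were updated through gene numbers to the GRCm38.p6 RefSeq table, which held 20351 of the 20380. No gene was named from a probe set with several symbols. Each of the 12393 genes was represented by the probe set with the highest mean signal, and the text says where another probe set of a named gene reached 244 with a far smaller ratio or the other sign in the pair named, unless the floor limited that ratio. This holds for ratios of B-DNA over mock and not for those between mock arrays, where other probe sets may differ. The floor was the 40th percentile of all scaled values, 122, and lower values were set to it before taking log2. Signals at that level were treated as having no measured order, which was not tested. The number of arrays limits the precision of every value.

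Without replicates in any group, the B-DNA array of a genotype was compared with its mock array as a ratio only. Genes were counted at 2-fold or more with the higher value at 244 or more. Tests used all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg threshold 0.05) on 9626 genes. The average response had genotype as a block and 3 residual degrees of freedom. The dependence on Tbk1 and on Ikbke came from 1 fit with a block for genotype and an interaction of treatment with each gene, whose error is the remaining 3-way interaction with 1 residual degree of freedom, moderated across genes (prior degrees of freedom 5.34). Level differences used the mean of both arrays of a genotype, with 1 residual degree of freedom. Nothing says that arrays came from separate cultures or embryos, so p-values measure only the spread between these arrays.

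The comparisons, the rule for named genes, the alternatives and 23 gene lists were fixed before the data were examined. Lists with 5 or more measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated one, over 60 tests. The estimated version uses only the residual degrees of freedom of the fit, 1 for the dependence fits and 3 for the average. It can therefore hardly call a list. The preset version takes the genes of a list as nearly independent. Genes that respond together are not, so its p-values are likely too small. For single pairs of arrays, a list's median was ranked among 10000 random lists of the same size drawn from genes of similar mean expression. Named were the 16 highest and 8 lowest genes in WT cells, the 5 highest and 5 lowest in each other genotype, up to 8 per sign in each limma comparison, 4 per sign between mock arrays, up to 4 members per list discussed together with members that differed in another genotype, and a fixed set of interferon and NF-kB genes. The cholesterol genes Cyp51, Dhcr7, Idi1, Sc5d and Stard4 and the Ikbke result of Il11 are given in addition, chosen after their values were seen. Where a list had many such members, examples are given.

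The fits were tested on simulated data built on the mean levels of the 9626 genes with 200 changed genes, 50 at each size. The changed genes were drawn from those well above the floor by mean mock level, and changes of 2 or more all went upward. Recovery of genes with values under the floor, such as 94 of the 199 called for Tbk1, was therefore not tested. The outcome depended on the spread that was put in, so 3 versions were run. With variances drawn from the prior that eBayes fitted, the Tbk1 dependence fit called 0 of 50 genes changed by 1 on the log2 scale, 30 of 50 at 2, 48 of 50 at 3 and 50 of 50 at 4, with 1 of 9426 unchanged genes called. With the shrunken variances it called 9, 50, 50 and 50, and with the raw residual variances it called none at any size. The average fit called 32, 42, 47 and 49 of 50 with the prior version. The level fit called none at any size with the prior version and with raw residuals, and 0, 36, 50 and 50 with shrunken variances. The prior version was adopted after the other versions had been seen, because shrunken variances are too even and raw residuals with 1 degree of freedom count chance spread again. The 2-fold rule picked 28 of 50 genes changed by 1, all 50 at the larger sizes and 69 of 9426 unchanged genes in the simulated WT pair of the prior version.

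Alternatives were no further scaling, quantile normalization, scaling to the median, floors at the 20th and 60th percentile, a pseudocount in place of the floor, every probe set on its own, fold thresholds of 1.5 and 3, other filters, eBayes with trend or robust, other designs and leaving out pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Leave-one-out fits of the Tbk1 dependence and the fit without the Ikbke interaction that they rest on, removal of marker lists, removal of genes far above the other mock arrays on the WT mock array, and the subset of interferon-stimulated genes above the floor on all 4 mock arrays were added after the data had been seen.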

Results

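Gene expression was measured on Affymetrix arrays in mouse embryonic fibroblasts, which are mesenchymal cells grown out of embryos. The cells were wild type (WT), lacked Tbk1, lacked Ikbke, or lacked both genes, giving 4 genotypes. Tbk1 and Ikbke encode related kinases that activate the interferon regulatory factors. Cells of each genotype were either mock transfected or transfected for 4 h with B-DNA, a synthetic right-handed DNA made of alternating A and T. Each of the 8 combinations was measured on 1 array, so no ratio between a B-DNA array and its mock array has a replicate check, and no p-value is given for one. The 2% trimmed mean of the deposited signal ranged from 140 on the Tbk1-/- Ikbke-/- mock array to 255 on the Tbk1-/- mock array, and every array was scaled to 500. Signals below are scaled, and values under a floor of 122 were set to the floor, so that a ratio against such a value is given as "at least". A gene was counted as higher or lower when it differed 2-fold or more and its higher value reached 244. Of 12393 genes, 9626 reached the floor on 1 or more arrays.

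The targeted genes were examined on every array. The brighter of the Tbk1 probe sets read 501 and 989 in WT cells (mock, then B-DNA), 472 and 910.0 in Ikbke-/- cells, 226 and 305 in Tbk1-/- cells, and 290.0 and 390 in Tbk1-/- Ikbke-/- cells. Both Tbk1-/- genotypes were thus below both Tbk1+/+ genotypes at each treatment. The Ikbke probe set lay under the floor on all 8 arrays and checks nothing. Whether either probe set lies in the deleted part of its gene is not known here. Xist, the RNA that coats the inactive X chromosome in female cells, read 3002 and 3766 in WT cells and 2950.1 and 3149 in Tbk1-/- cells. It read 138 and 161 in Ikbke-/- cells and 209 and 180 in Tbk1-/- Ikbke-/- cells. The Y-linked gene Eif2s3y went the other way, from 1.5 to 3.6 in WT and Tbk1-/- cells and from 153 to 287 in the Ikbke-/- genotypes. The Ikbke genotype and the sex of the embryos therefore cannot be told apart in any comparison below.

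In WT cells, B-DNA was followed by higher signals of interferon-stimulated genes, the genes that interferon turns on through the Stat transcription factors. Ifit1, which binds foreign RNA, went from 600.0 to 23925 (log2 ratio 5.32), and Ifit3 from 314 to 19679 (5.97). Rsad2, the antiviral enzyme viperin, went from 400.0 to 20460 (5.68). Ifih1, a sensor of double-stranded RNA, went from 273 to 13655 (5.65). Of the 45 measured interferon-stimulated genes on the list fixed beforehand, 43 were higher and none was lower, with a median log2 ratio of 3.26.

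The remaining WT genes with the highest ratios were of the same kind. Ifit2, Cmpk2 and Mx1 lay under the floor on the mock array and were at least 68.1-fold, 60.1-fold and 59.3-fold higher. Among the interferon-induced GTPases, Igtp (log2 ratio 5.45), Iigp1 (5.41), Gbp2 (5.09), Irgm2 (at least 5.24) and Ifi47 (at least 5.08) were higher. Oasl1 (5.20), Oasl2 (at least 5.28) and Usp18 (5.11), a protease that limits interferon signalling, were higher too. The transcription factors Irf7 and Stat2 had ratios of 4.27 and 3.16. Ifnb1, the interferon beta gene, read 99.5 and 221, and the higher value was under 244, so it was not counted.

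Other groups differed in WT cells as well. Of 24 chemokine and cytokine genes, 11 were higher and 1 was lower. Cxcl10, a T cell attractant, went from 440 to 16600 (5.24), Ccl5 from 841 to 15819 (4.23), and Il6 from 345 to 1861 (2.43). Cxcl11 and Cxcl9, under the floor on the mock array, had log2 ratios of at least 4.51 and 4.46. Of 13 genes of MHC class I antigen presentation, 10 were higher, led by the peptide transporter Tap1 (3.53) and the immunoproteasome subunits Psmb8 (3.43) and Psmb9 (at least 3.08). Among 21 genes of nucleic acid sensing, 5 were higher, among them Tlr3 (at least 4.16), Myd88 (1.67), Sting1 (1.51) and Irf5 (1.38). Of 27 NF-kB target genes, 5 were higher, among them Irf1 (2.12), Vcam1 (1.52) and Birc2 (1.33), while Nfkbia read 0.19. Ccne1, which encodes cyclin E, went from 353 to 2003, and the death receptor gene Fas had a ratio of 1.83.

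Macrophage genes were among the lowest WT ratios. Lyz1 and Lyz2, the lysozyme genes of macrophages and neutrophils, went from 5903 to 651 (-3.18) and from 4991 to 1205 (-2.05). The Lyz1 probe set may also detect related sequences. C1qa, a complement component made by macrophages, went from 1191 to 303 (-1.98). Of 18 macrophage and leukocyte markers, 11 were lower after B-DNA. On the WT mock array 15 of the 18 reached 244, on the WT B-DNA array 12 did, and on each of the other arrays 1 or 2 did. The other low genes were Gas1 (-2.61), Mthfd1 (at least 5.81-fold lower), Msmo1 (-2.38), Ms4a7 (-2.15), Tcim (at least 4.37-fold lower) and Maff (at least 4.09-fold lower). A further Mthfd1 probe set gave -0.24. In all, 315 genes were higher and 182 lower in WT cells. Without further scaling of the deposited values, which moves WT log2 ratios by -0.40 where no floor enters, 178 were higher and 726 lower, and the NF-kB list's median of 0.19 turned to -0.21 (0.17 after subtracting the median of all genes).

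**Figure D1:**
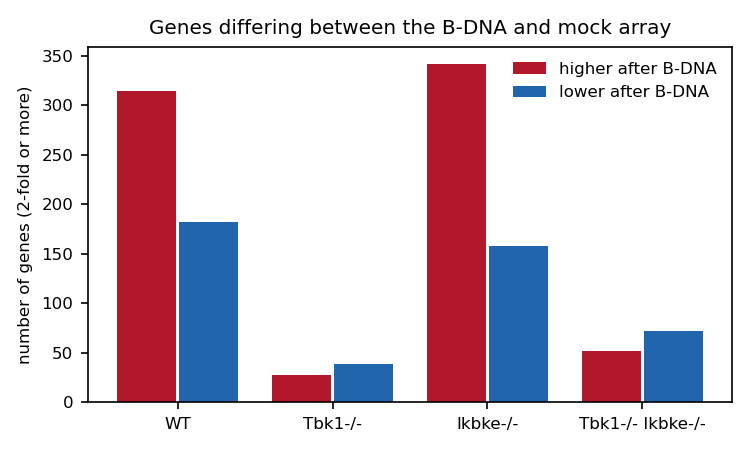
Bars give the number of genes that were 2-fold or more higher (red) or lower (blue) on the B-DNA array than on the mock array, for each genotype, with 1 array per genotype and treatment and so no error bars. WT cells had 315 higher and 182 lower genes, Tbk1-/- cells 28 and 39, Ikbke-/- cells 342 and 158, and Tbk1-/- Ikbke-/- cells 52 and 72.

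In Tbk1-/- cells, none of the 45 interferon-stimulated genes was higher after B-DNA. Ifit1 read 65.1 and 104, Ifit3 65.5 and 35.4, and Mx1 40.8 and 57.8, all under the floor. Rsad2 read 157 and 88.6. Cxcl10 had a log2 ratio of 1.02, from 161 to 328, and lay under 2-fold with other scalings, at 0.85 without further scaling, 0.94 after quantile normalization and 0.99 when scaled to the median. Ccl5 was lower, from 538 to 204 (-1.40).

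A total of 28 genes were higher and 39 lower in Tbk1-/- cells, or 22 and 105 without further scaling. In simulated data the same rule picked 69 of 9426 unchanged genes with the prior version, and 12 and 152 with shrunken and raw residual variances. The 67 genes in Tbk1-/- cells lay under the counts of the prior and raw residual versions and above that of shrunken variances. The spread put in came from these same arrays, so the simulation cannot say whether the 67 are noise. Single ratios below may be noise. Gas1, a growth arrest protein, had the highest ratio at 2.76, opposite to its WT ratio of -2.61, followed by C1qtnf1 and Cdr2l (at least 3.27-fold and 2.87-fold), Chst12 (at least 2.74-fold) and Medag (1.42). The lowest were Cklf (-2.63), the cytokine gene Il11 (-1.87), Arc (-1.61), Serpinb2 (at least 2.99-fold lower) and U90926 (at least 2.68-fold lower). Of 26 immediate early genes, which answer within minutes to growth factors and stress, 4 were lower: Fos (-1.40), Fosb (-1.18), Dusp6 (-1.11) and Atf3 (-1.09). In WT cells 4 and in Ikbke-/- cells 3 of the 26 were lower too, among them Fos (-1.02 and -1.15). A further Cklf probe set gave -0.32, and a further Gas1 probe set went from 598 to 1196. None of 13 MHC class I genes differed, nor did any of 21 sensing genes. Vcam1 (-1.05) was lower, the only one of 27 NF-kB target genes to differ, and the list's median was -0.18.

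In Ikbke-/- cells the interferon-stimulated genes were again higher. Of the 45, 44 were higher and none was lower, with a median log2 ratio of 4.23. Rsad2 went from 123 to 23165 (7.55), Ifih1 from 128 to 14101 (6.78), and Ifit3 from 288 to 24582 (6.42). Ifit2 and Mx1 were at least 88.9-fold and 83.4-fold higher. Cxcl10 (5.55), Ccl5 (4.30) and Il6 (at least 2.66) were higher, as were 10 of 13 MHC class I genes, with Tap1 at 4.00.

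Altogether 342 genes were higher and 158 lower in Ikbke-/- cells, or 271 and 424 without further scaling. With WT cells they shared 230 higher genes, where independent lists would share 11.2, and 36 lower genes, where independent lists would share 2.99. Across the 9626 genes, the Pearson correlation of the log2 ratios in WT and Ikbke-/- cells was 0.74, and genes are not independent replicates. Of the 230 shared genes, 175 had the higher ratio in Ikbke-/- cells, with a median difference of 0.26 (SD 0.50 across genes). Outside the shared genes, Cxcl9 lay under the floor on both mock arrays and read 2682 after B-DNA in WT and 203 in Ikbke-/- cells, and Cxcl1 had ratios of 1.38 in WT and -0.80 in Ikbke-/- cells. The lowest Ikbke-/- ratios were those of the interleukin 1 receptor gene Il1r1 (-2.00), Dnajc1 (-1.91), Dmp1 (from 440 to under the floor), Chst1 (at least 3.46-fold lower) and Msmo1 (-1.76). A further Dnajc1 probe set gave -0.04. No leukocyte marker differed in these cells.

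In Tbk1-/- Ikbke-/- cells, 1 of the 45 interferon-stimulated genes, Samhd1 (1.12), was higher and 1, Oasl1 (at least 2.06-fold), was lower. Other Samhd1 probe sets gave ratios from -1.32 to 0.14. Ifit1 read 149 and 138, Ifit3 235 and 265, and Mx1 46.1 and 62.2. Of the 24 chemokine and cytokine genes, 4 were higher. Cxcl1 went from 130 to 1078 (3.05), Ccl7 from 279 to 958 (1.78), Ccl2 from 1538 to 3161 (1.04), and Cxcl2 was at least 4.22-fold higher. Irf1, an interferon regulatory factor gene driven by NF-kB, went from 1569 to 4743 (1.60).

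In these cells 52 genes were higher and 72 lower, or 117 and 18 without further scaling. The total of 124 lay above the 69 and 12 unchanged genes picked by the same rule in simulated data with prior and shrunken variances. It lay under the 152 picked with raw residual variances. The simulation cannot say whether these genes are noise, and single ratios here may be noise. Besides Irf1, the NF-kB target genes Zfp36 (1.60) and Icam1 (at least 2.96-fold) were higher, 3 of 27 in all. Of 26 immediate early genes, Atf3 (1.37) and Myc (1.10) were higher. The NF-kB list's median was 0.23, above 99.9% of random lists of matched expression, but cell cycle and immediate early genes also lay at or above 99.7% in this pair, and the NF-kB list lay as high in WT and Ikbke-/- cells (99.975% and 99.98%). On the Tbk1-/- Ikbke-/- mock array the same list lay low, with 10 of 27 genes 2-fold or more under the WT mock array and 1 above it. Serf1 and Nme6 were at least 5.69-fold and 3.79-fold higher, and the lowest ratios were those of Acaa1a (-1.83), Gys1 (-1.75), Slc2a3 (-1.56), Sema7a (-1.50) and Fxr2 (-1.48). Further probe sets gave -0.70 for Gys1 and 0.66 and -0.94 for Serf1, and another of Serf1 went from 304 to under the floor.

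**Figure D2:**
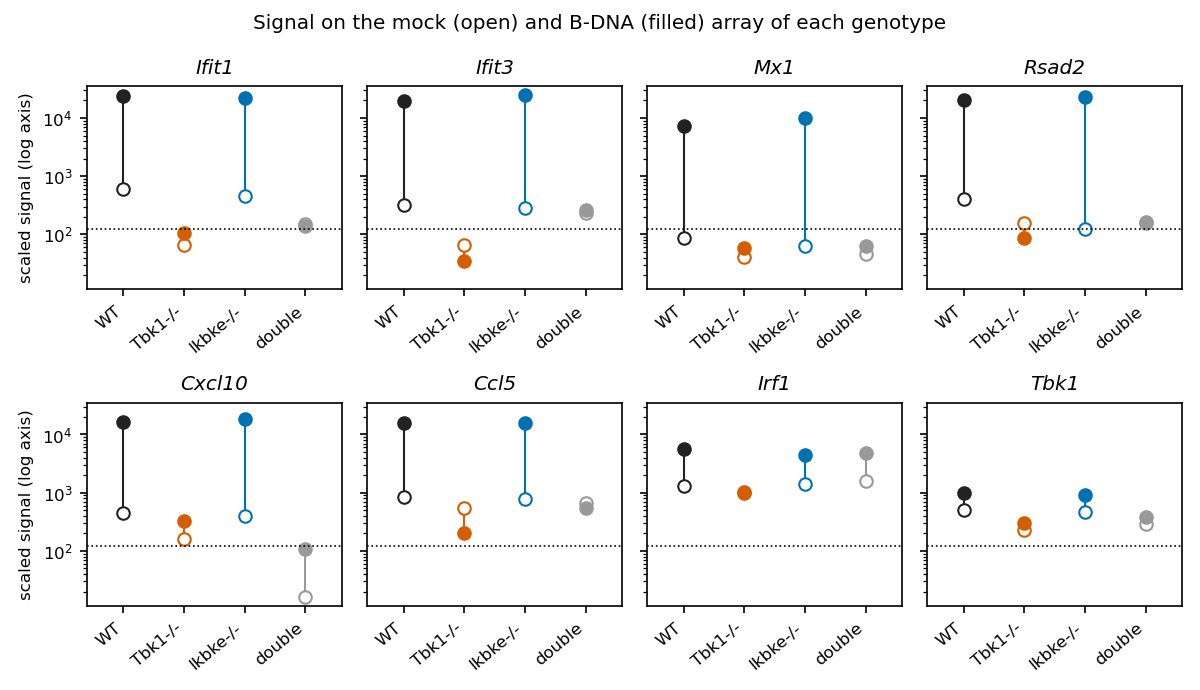
Each panel shows the scaled signal (log axis) of 1 gene on the mock array (open point) and the B-DNA array (filled point) of WT, Tbk1-/-, Ikbke-/- and Tbk1-/- Ikbke-/- cells ("double"), with 1 array per point and the floor of 122 as a dotted line. Ifit1 reached 23925 and 21838 after B-DNA in WT and Ikbke-/- cells and read at most 149 in the others, while Irf1 reached 4743 in the cells lacking both genes.

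The dependence of the response on Tbk1 was tested across the 4 pairs of arrays. In 176 genes the log2 ratio was lower in the Tbk1-/- pairs than in the Tbk1+/+ pairs, and in 23 genes it was higher (limma, Benjamini-Hochberg adjusted over 9626 genes). Of the 176 genes, 166 were higher after B-DNA in both WT and Ikbke-/- cells. Ifih1, above the floor on all 8 arrays, had a difference of -6.05 (SE 0.29, adjusted p = 4.91e-04 by limma). Rsad2 (-6.79), Ifit2 (-6.25), Oasl1, Mx1, Iigp1, Ifit3 and Cmpk2 (the last 5 between -6.19 and -5.90) had 1 or more values under the floor, so neither the order nor the spread of their differences was measured. Of the 199 genes, 94 had such a value, and the other 105 were also called among the 6665 genes above the floor on all arrays, where 162 genes had a lower and 83 a higher ratio. Of the 45 interferon-stimulated genes, 41 had a lower ratio (45 adjusted over the list alone), as did 10 of 13 MHC class I genes (11 adjusted over the list alone).

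Among the remaining groups, 5 of 24 chemokine and cytokine genes passed the test with a lower ratio in Tbk1-/- pairs (8 adjusted over the list alone), among them Ccl5 (-5.11), and Cxcl10 (-4.88) and Il6 (-2.61) with values under the floor. Of 21 sensing genes 3 passed (5 adjusted over the list alone), with Myd88 at -2.09, Sting1 at -1.51, and Tlr3 at -4.24 with values under the floor. Ccne1, the only one of 37 cell cycle genes to pass, had a difference of -2.30. No NF-kB target gene passed over all genes (3 adjusted over the list alone), and Irf1 had a difference of -1.05 with an adjusted p of 0.33 by limma. In the opposite direction, the 23 genes included Cdr2l (2.45), AW209491 (2.05), Jade1 (1.83), Fzd6 (1.77), Nanp (1.76), Foxc2 (1.73), Cdc42ep1 (1.70) and Bhlhe40 (1.67). Foxc2, a transcription factor of mesenchyme, had ratios of -2.01 in WT and -1.19 in Ikbke-/- cells, against -0.31 in Tbk1-/- and 0.57 in Tbk1-/- Ikbke-/- cells. Cdr2l and Fzd6 had values under the floor, and the other probe sets of Jade1 lay under it on both WT arrays.

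As lists, interferon-stimulated genes, MHC class I, chemokine, sensing and p53 target genes had lower log2 ratios and leukocyte markers higher ones in the Tbk1-/- pairs (camera, adjusted p from 7.32e-72 to 0.041 with a preset correlation of 0.01). None of these 6 calls held (adjusted p = 0.89 by camera with an estimated correlation), but that version has 1 residual degree of freedom and could hardly call any list. The preset p-values are likely too small, since they take genes that respond together as nearly independent. The leukocyte markers had a median of -1.32 in WT cells and 0 in the other genotypes. Of the 26 p53 target genes only 2 passed singly (limma), and Tap1 is on both the p53 and the MHC class I list. The limma test of single genes also has 1 residual degree of freedom, and leaving out a pair requires a model without the Ikbke interaction. That model called 104 genes with all pairs and none when any 1 of the 4 was left out, although all 199 genes kept their sign and the median difference of interferon-stimulated genes (-3.72 with all pairs) lay between -4.04 and -3.29. No gene was called either without the filter on low genes or with additive genotype factors. The 199 genes had been picked on these same pairs, so that their kept sign is no support.

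The dependence on Ikbke was tested in the same fit, and limma called no gene after adjustment over all genes (435 genes had an unadjusted p under 0.05, lowest adjusted p 0.98). Of the 24 chemokine and cytokine genes 1 passed when adjusted over the list alone, Il11, which was singled out after its values were seen. It lay under the floor on the WT B-DNA array and on both Tbk1-/- Ikbke-/- arrays, so its difference was not measured. Rsad2 had log2 ratios of 7.55 in Ikbke-/- and 5.68 in WT cells, and 0.02 in Tbk1-/- Ikbke-/- cells. The gap between Ikbke-/- and WT cells lay mostly in the mock arrays, where Rsad2 read near the floor in Ikbke-/- cells, while the B-DNA signals were close. For interferon-stimulated genes the median difference of Ikbke-/- less WT ratios was 0.39. Leukocyte markers, immediate early genes, interferon-stimulated genes, NF-kB target genes, unfolded protein and amino acid stress genes and p53 target genes had higher log2 ratios in the Ikbke-/- pairs as lists (camera, adjusted p from 6.33e-09 to 0.021 with a preset correlation). None of the 6 held (adjusted p = 0.89 by camera with an estimated correlation), but that version has 1 residual degree of freedom and could hardly call any list. The preset p-values are likely too small here as well. The leukocyte markers were seen on the WT arrays alone, immediate early genes had medians of -0.19 in WT and -0.06 in Ikbke-/- cells, and sex goes with Ikbke genotype here.

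The average response over the 4 genotypes was tested next. Over all 9626 genes limma called none (761 genes at an unadjusted p under 0.05, lowest adjusted p 0.61). As lists, interferon-stimulated, MHC class I, chemokine, p53 target and NF-kB target genes were higher after B-DNA, and genes of cholesterol synthesis and uptake (adjusted p = 3.88e-10), heat shock genes and leukocyte markers were lower (camera, adjusted p from 1.90e-18 to 0.024 with a preset correlation). None of the 8 held (adjusted p = 0.89 by camera with an estimated correlation), but that version has only 3 residual degrees of freedom and little power. The preset p-values, that of the cholesterol list among them, are likely too small. Of these lists only the cholesterol list had members that passed when adjusted over the list alone, with 8 of its 18 genes lower (limma). That adjustment takes no account of the other lists and comparisons looked at in the same way. Cyp51 fell by 0.65 on the log2 scale (SE 0.10, adjusted p = 0.026 by limma over the list alone), lower in 4 of 4 pairs. Msmo1 fell by 1.40 and Hmgcs1, the enzyme that makes HMG-CoA, fell by 0.84, each lower in 4 of 4 pairs. Hmgcs1 had only -0.11 in Tbk1-/- Ikbke-/- cells. Without further scaling, log2 ratios of that pair move by 0.19 where no floor enters, so its sign there rests on the scaling. Sqle, squalene epoxidase, fell by 0.64 and was lower in 3 of 4 pairs.

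The other members of the 8 were Sc5d, Stard4, Idi1 and Dhcr7, which like Cyp51 are named here after their values were seen. The list's median log2 ratio was -0.31 in WT, -0.77 in Tbk1-/-, -0.73 in Ikbke-/- and -0.10 in Tbk1-/- Ikbke-/- cells, the last being 0.09 without further scaling. On the mock arrays the list already lay higher than in WT cells, with a median of 0.65 in Tbk1-/- cells (5 of 18 genes 2-fold higher) and 0.91 in Ikbke-/- cells (8 of 18), the genotypes with the lowest ratios, so a high start cannot be told from a fall.

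**Figure D3:**
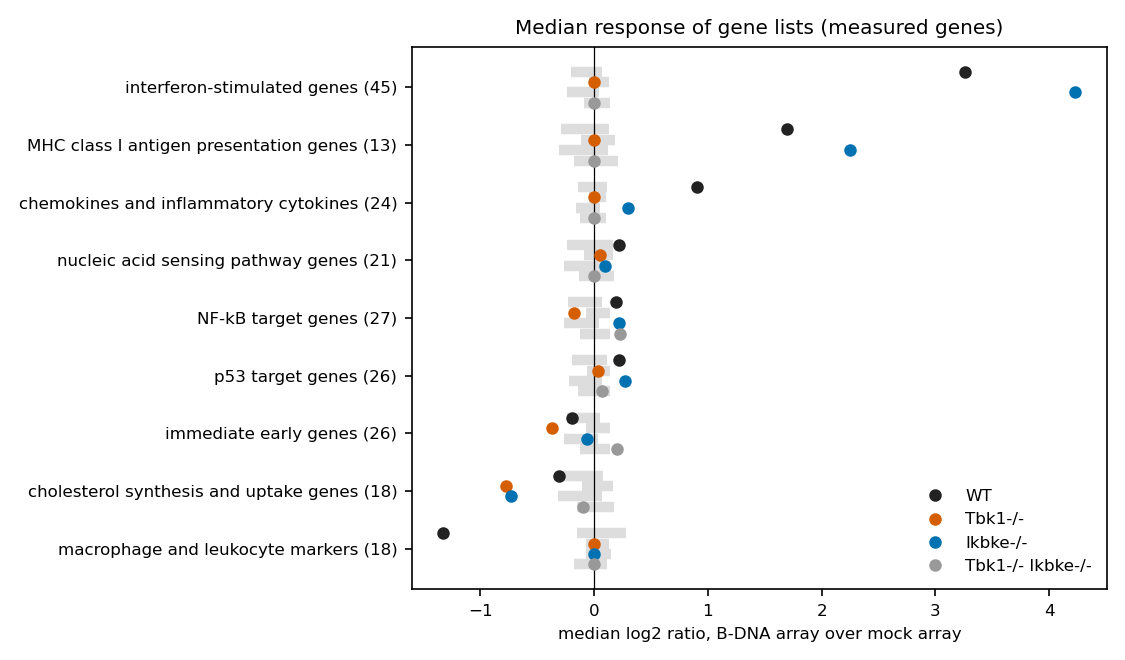
Points give the median log2 ratio of B-DNA over mock for 9 gene lists in each genotype (1 array per treatment), and grey bars the central range of 10000 random lists matched on expression. Interferon-stimulated genes sat at 3.26 in WT and 4.23 in Ikbke-/- cells and at 0 in both Tbk1-/- genotypes, and leukocyte markers at -1.32 in WT cells only. A median of 0 can come from the floor. On the B-DNA arrays, 20 of 45 interferon-stimulated genes reached it in Tbk1-/- and 28 in Tbk1-/- Ikbke-/- cells.

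Before B-DNA, the mock arrays of the mutants also differed from the WT mock array. Cnmd, a cartilage protein gene, was at least 19.9-fold higher in Tbk1-/- and at least 155-fold higher in Ikbke-/- cells, at signals of 2434 and 18912. Ikbke-/- cells also had more Col9a1 (log2 ratio 5.27) and Matn4 (5.00), both of cartilage matrix, and Pcp4 (at least 4.42), and 9 of 11 chondrocyte and bone markers were higher. Tbk1-/- Ikbke-/- cells had more Dcn (4.17), Ptn (4.16), Wfdc18 (3.92) and Plac8 (at least 3.66), and less Gjb2 (-5.21) and Lgals3 (at least 32.4-fold). Tbk1-/- cells had more Cd24a (3.78), Rgs17 (at least 3.59) and Npnt (3.56), and less Aqp1 (at least 29.6-fold) and Prrx1 (at least 23.1-fold).

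Compared with the WT mock array, 215 genes were higher and 321 lower in Tbk1-/- cells, 222 and 301 in Ikbke-/- cells, and 535 and 530 in Tbk1-/- Ikbke-/- cells. Lyz1 and Lyz2 were among the lowest in all mutants, and 15 of 18 leukocyte markers were lower in each, all set against the same WT mock array. Of 26 immediate early genes, 18 were lower on the Tbk1-/- Ikbke-/- mock array and 9 were higher on the Tbk1-/- mock array, and Fos read 608 on the Tbk1-/- Ikbke-/-, 4557 on the Tbk1-/- and 1406 on the WT mock array. Of 37 cell cycle genes, 18 were lower in Ikbke-/- cells and 11 were higher in Tbk1-/- Ikbke-/- cells. Averaged over treatments, limma called no gene for level differences with Tbk1 genotype (365 at an unadjusted p under 0.05) or Ikbke genotype (238). In simulated data this fit called no changed gene at any size tried with 2 of 3 kinds of spread, so these counts of 0 say little about levels.

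**Figure D4:**
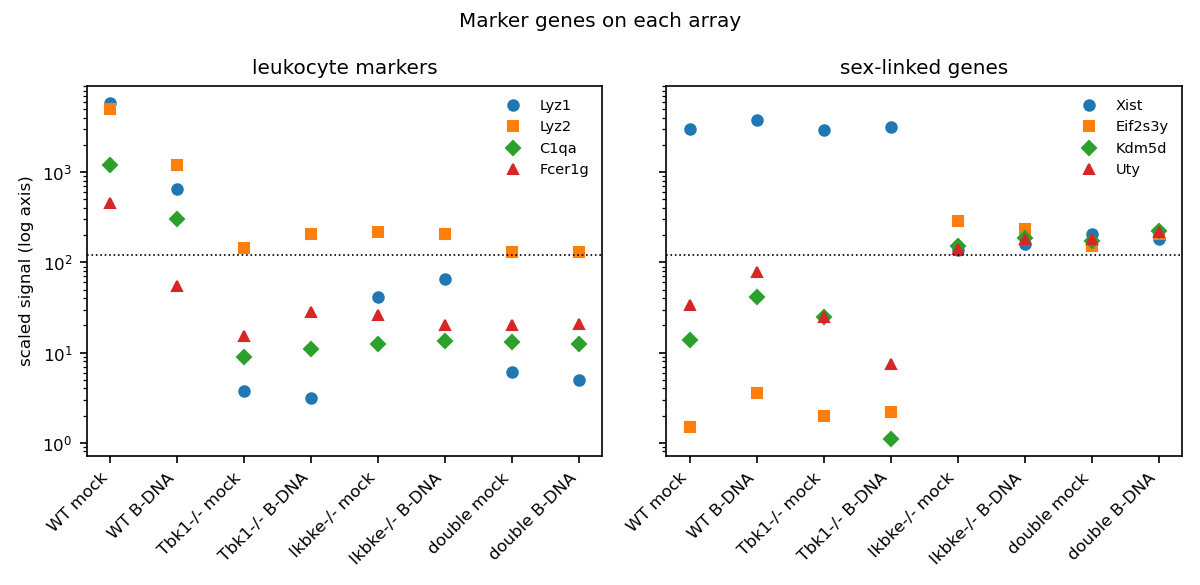
Scaled signal (log axis) on each of the 8 arrays for 4 leukocyte markers (left) and 4 sex-linked genes (right), 1 array per point, with the floor of 122 as a dotted line. Lyz2 read 4991 and 1205 on the WT arrays and at most 218 on the others, and Xist read at least 2950.1 in WT and Tbk1-/- cells and at most 209 in the rest.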

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

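The tests on NF-kB target genes and on leukocyte markers were chosen after the results they bear on had been seen, and the tests of whether B-DNA acted and of other groupings were chosen before.

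In 199 genes the response to B-DNA differed with Tbk1 genotype by a test of the difference itself. Among the negative log2 differences (Tbk1-/- less Tbk1+/+ pairs) were those of Rsad2 (-6.79), Ifit2 (-6.25), Oasl1 (-6.19), Mx1 (-6.14), Iigp1 (-6.12), Ifit3 (-6.10), Ifih1 (-6.05) and Cmpk2 (-5.90). Among the positive ones were those of Cdr2l (2.45), AW209491 (2.05), Jade1 (1.83), Fzd6 (1.77), Nanp (1.76), Foxc2 (1.73), Cdc42ep1 (1.70) and Bhlhe40 (1.67). Values under the floor were set to it, so these differences have no measured order where such values enter, as in 94 of the 199 genes. With camera and a preset correlation, 6 gene lists differed with Tbk1 genotype and 6 with Ikbke genotype. None held with an estimated correlation (adjusted p = 0.89 by camera), a version with 1 residual degree of freedom that could hardly call any list. The preset version takes genes of a list as nearly independent and likely calls lists too readily. Of the 3 ways to pair the 4 genotypes, 1, the real one, gave as many genes, with 199 (129 with the error term used for pairing WT with Tbk1-/- Ikbke-/- cells) against at most 0 for the others, and 3 pairings are too few for a share under 0.05.

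Interferon-stimulated genes were not higher after B-DNA in either Tbk1-/- genotype, and a candidate explanation is that B-DNA did not act on those cells at all. Genes lower in both WT and Ikbke-/- cells served as a readout other than interferon. It is not independent of Tbk1, since 13 of the 36 passed the test of Tbk1 dependence. Genes that need Tbk1 would not fall without it even if B-DNA acted. In Tbk1-/- cells these 36 genes had a median log2 ratio of -0.17, at the 0 percentile of 10000 random matched lists. Of them 25 were lower, but only 3 by 2-fold. The rank was not particular to them, since immediate early, cholesterol and NF-kB target genes also lay at the 0 percentile in this pair. The immediate early and cholesterol lists started high on the Tbk1-/- mock array, with medians of 0.70 and 0.65 over WT. Fos, Maff and Msmo1 are among the 36. An unusual mock array can thus not be told from an action of B-DNA there. In Tbk1-/- Ikbke-/- cells their median was 0.01, at the 45.3 percentile, so that a failure of B-DNA to act there stays open. Loss of Tbk1 itself, which the design names, also stays open, and sex does not follow Tbk1 genotype on these arrays.

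NF-kB target genes had a median log2 ratio of 0.23 in Tbk1-/- Ikbke-/- cells and -0.18 in Tbk1-/- cells, a difference that was not tested. A scaling factor moves all genes of an array alike, and the median lay at or above the 99.89 percentile of random matched lists of the same arrays, which argues against scaling as the whole cause, but cell cycle genes (99.71) and immediate early genes (99.7) ranked high too, so the rank is not particular to NF-kB. A low start is consistent with the values, since on the Tbk1-/- Ikbke-/- mock array the list's median level lay at -0.798 relative to the mean of the other mock arrays, with 21 of 27 members lower, and still at -0.36 after B-DNA. Immediate early genes lay at -1.75 and -1.26 in the same comparison. An unusual state of that mock culture and a response independent of both kinases both stay open, since there is 1 array of each.

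Macrophage and leukocyte markers were high on the WT mock array and lower on the WT B-DNA array. Of the 11 markers far above the other mock arrays, 11 were lower after B-DNA, with a median log2 ratio of -1.55 and a range from -3.18 to -0.64. These markers were picked for being high on the WT mock array, so the count restates the observation, and fewer leukocytes on the B-DNA array, a response of leukocytes to B-DNA and chance on 1 array all stay open. Lyz2 read 4991 and C1qa 1191 on the WT mock array. Leukocytes were not needed for a response of this size, since Ikbke-/- cells, whose arrays lacked these markers, had a median log2 ratio of interferon-stimulated genes of 4.23 against 3.26 in WT cells. A share of leukocytes in the WT response stays open, since both WT arrays carried the markers.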

How the results depend on the processing

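The leave-one-out fits of the Tbk1 dependence and the subset of interferon-stimulated genes were chosen after the result was seen. Of the alternatives for counts and medians that answer a comparison, 102 stayed within 1.5 times the count, both directions together, or 1.5-fold of the median, and 45 did not. Many of the 102 were counts of 0 genes or medians near 0 in the Tbk1-/- genotypes. The tally therefore says little about the results with a response. Counts of genes that differed 2-fold, in the order WT, Tbk1-/-, Ikbke-/- and Tbk1-/- Ikbke-/- cells (497, 67, 500 and 124), became 1213, 459, 978 and 716 with the floor at the 20th percentile, 294, 25, 313 and 45 at the 60th, 290, 26, 320 and 40 with a pseudocount, 798, 130, 766 and 247 with every probe set on its own, 1333, 422, 1372 and 788 at 1.5-fold, and 171, 5, 191 and 12 at 3-fold. Without further scaling they were 904 in WT and 127 in Tbk1-/- cells, where the shift of all arrays moves genes over the threshold. The median of interferon-stimulated genes became 4.07 in WT cells with the floor at the 20th percentile, and in Ikbke-/- cells 3.58 with the floor at the 60th, 3.58 with every probe set, and 3.49 for members above the floor on all 4 mock arrays. Those last members had a median of 3.06 in WT, 0.14 in Tbk1-/- and -0.03 in Tbk1-/- Ikbke-/- cells. The Tbk1 dependence had 120 genes without further scaling, 48 with the floor at the 20th percentile and 389 with a pseudocount, of which 120, 46 and 199 were among the 199. Higher ratios in Tbk1-/- pairs, 23 in the main result, numbered 18, 1 and 96 in these, 60 with the floor at the 60th percentile, 83 among genes above the floor on all arrays and 53 with trend. limma called 0 without the filter on low genes (prior degrees of freedom 0.42 in place of 5.34), 0 with additive factors, 104 without the Ikbke interaction, and in that model from 0 to 0 leaving out 1 pair (1175 to 1621 genes at an unadjusted p under 0.05), with the sign of all 199 kept and prior degrees of freedom from 0.85 to 0.88 (2.58 with all pairs). Level differences had 36 (Tbk1) and 1 (Ikbke) genes with a pseudocount, and 43 and 34 with the 8 arrays as units, which counts both arrays of a genotype as replicates. Of 20 list calls, 0 held with an estimated correlation, which leaves camera 1 or 3 residual degrees of freedom and little power to call a list. For named genes 1038 alternatives kept the side of the threshold, 211 fell short of it and none turned the sign, with 113 of 247 short of it among the Tbk1 differences. These alternatives kept the probe set chosen for each gene, so they did not test other probe sets. In Tbk1-/- Ikbke-/- cells other probe sets turned the sign for Serf1 (-0.94 against 2.51) and Samhd1 (-1.32 against 1.12). Except where stated, the cause was not tested. Ratios of genes near the floor of 122 are limited by signal over background. By replicate number, no paired analysis was possible because the groups share only number 1. Arrays were paired by genotype, and without that block limma also called 0 genes for the average response.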

Other observations

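The genes named in this part were chosen after their values were seen, and the test of other splits was chosen before.

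Among 26 p53 target genes, 5 were higher in Ikbke-/- cells after B-DNA, namely Tap1, which is also part of antigen presentation, Fas (2.24), Trp53inp1 (1.43), Bbc3 (1.15) and Apaf1 (1.14), the last 2 being parts of the cell death machinery, while Sesn1 (-1.13) was lower. Pdgfra, a growth factor receptor of mesenchymal cells, was lower in WT (-1.61, but -0.53 with a further probe set) and Ikbke-/- cells (-1.23) and read 0.14 and 0.02 in Tbk1-/- and Tbk1-/- Ikbke-/- cells, and its difference with Tbk1 passed (positive sign, adjusted p = 0.042 by limma). Msmo1 (1.34, adjusted p = 0.047 by limma) passed in the same direction. Like all calls of that comparison, these were lost when any 1 pair was left out together with the Ikbke interaction.

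Between B-DNA and mock arrays of a genotype, none of 28 unfolded protein and amino acid stress genes, 9 constantly used genes, 9 endothelial, 11 neural or 4 erythroid markers differed 2-fold in any genotype.

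For the average response, limma called 0 genes, so that 32 of 32 splits of the arrays gave as many by construction, which says nothing about chance. The highest other split gave 373 genes, and it parts only the WT and Ikbke-/- pairs, which points to the response those genotypes share.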
